A study of Rattus norvegicus with 8 samples.

How the data were processed

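The series measured gene expression in the medial collateral ligament of the rat knee on 8 one-colour oligonucleotide arrays, 2 in each of 4 groups: loaded control, loaded healing, unloaded control and unloaded healing. Ligaments were taken at 3 weeks. Per the labels, the loaded controls had sham surgery and the unloaded controls had none, and unloading of the healing animals began 24 h after surgery. The labels do not say whether the arrays of a group come from separate animals, from pools of animals or from repeats of 1 sample. The SEs and p-values measure the spread between arrays, which for repeats of 1 sample would be technical spread only.

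The deposited values are linear signal intensity per probe set, in a table of 8799 probe sets by 8 arrays. The authors' values had already been scaled between arrays, since the 2% trimmed mean lay between 500.3 and 500.6 on every array. The software and the method that summarised the probes are not given in the sources used here. All 8 columns of the table were used and 0 were left out.

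Gene symbols came from the array's probe table, and their Entrez identifiers were matched to the RefSeq gene table of rat assembly GRCr8. Of the probe sets, 7018 carried 1 symbol, 308 several and 1473 none. The match by identifier covered 6994 of those with 1 symbol and changed 0 symbols. The probe sets measure transcripts, so no genomic positions are given, and the probe sequences were not used here.

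The 59 control probe sets of the array were set aside. An offset of 45.8, the 10th percentile of all values, was added before taking log2, and the 40% of probe sets with the lowest mean log2 signal over all 8 arrays were removed. This left 5244 probe sets, of which 4175 carried 1 symbol and stood for 3228 genes. Fold changes and their standard errors (SE) include the offset, which shrinks the folds of dim probe sets. The number of arrays limits the precision of every value.

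A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes variances that follow mean intensity. It had 4 residual degrees of freedom and 5.81 prior degrees of freedom. The contrasts were healing against control in loaded rats, the same in unloaded rats, unloading in healing ligaments, unloading in control ligaments, the interaction (healing effect in unloaded minus loaded rats) and the healing effect averaged over loading. The tests were two-sided and p-values were adjusted by Benjamini-Hochberg over the 5244 probe sets within each contrast, with a threshold of 0.05. By chance, 262 probe sets would pass an unadjusted p of 0.05.

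There were 24 gene lists, with 1 probe set per gene (the brightest) and at least 4 measured genes in each. They were tested in 5 contrasts with camera at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists of a contrast. Beside it, camera was run with the correlation estimated from the data, and fry was run for change in one direction and in either direction. The groups, contrasts, lists, threshold and most alternatives were fixed before the data were examined. Named genes followed a rule fixed at the same time: for each contrast, the 10 largest rises and 10 largest falls past the threshold with 1 symbol and no overlap between the groups. For the interaction the largest differences in either direction were taken without that condition. From each list the rule added up to 4 members past the threshold, or, where none passed, 2 members given as values.

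The model was tested on simulated data with 50 changed probe sets per size of change. The data had the measured mean of each probe set, the model's own empirical Bayes variances and independent normal errors. That setting suits the model, so the shares may differ in real data. For the healing effect in loaded rats the model recovered 8% of true changes of 1 log2 unit, 56% of 2, 92% of 3 and 98% of 4. The false share of calls was 3.05% in that contrast and at most 7.95% in the other 3 pairwise contrasts.

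Alternatives fixed in advance were quantile normalization, median centring, no offset with a floor, an offset 4 times as large, no filter and a filter at 60%, a variance prior without the intensity trend or with a robust fit, a term for replicate number, a fit to the compared groups alone, averaged probe sets of a gene, and leaving out each array in turn. Added after seeing the data were a fit without the unloaded controls, scaling to the geometric mean of the BioC, BioDn and CreX spike-in control probe sets, for the control groups a fit without unloaded healing, unscaled, scaled to those controls, with the BioB controls added and with BioB alone, and the comparison of unloaded healing with loaded control. BioB was left out of the first scaling because a BioB probe set read 761 on unloaded healing 2 and 27208 on unloaded healing 1. Where an array was left out, its group kept 1 array, assumed to vary like the other groups.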

Results

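Expression was measured in rat medial collateral ligaments at 3 weeks, in 4 groups of 2 arrays that combine injury (healing or control) with weight bearing (loaded or hindlimb unloaded). Hindlimb unloading lifts the hind legs off the ground so that they carry no weight. The question, from the title and labels, is how unloading changes ligament healing. Values are signal intensities per probe set, and median signals ran from 238.7 to 315.9 over the 8 arrays.

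The unloaded control arrays stood apart from the rest. Across probe sets, the Pearson correlation of log2 signal with the other 6 arrays was 0.492 to 0.608, against 0.761 to 0.872 among those 6, and probe sets are not independent replicates. Within groups it was 0.825 for loaded controls, 0.841 for loaded healing, 0.834 for unloaded controls and 0.806 for unloaded healing. The 99th percentile of signal was 5494 and 5584 on the unloaded control arrays and 9218 to 11289 on the others. The actin 5'/3' control ratio, a sign of RNA or labelling quality, was 0.964 and 0.634 there and 0.237 to 0.529 elsewhere. The GAPDH 5'/3' ratio showed no such shift, at 0.953 and 0.712 there and 0.729 to 0.896 elsewhere. A BioB spike-in probe set read 7548 and 5443 there, 17173 and 20544 on the loaded control arrays and 761 on unloaded healing 2, while a BioC probe set read 9723 and 8829 there and 9883 and 11174 on the loaded control arrays. Of the 200 probe sets brightest on the other 6 arrays, 121 were lower in unloaded than in loaded controls by more than 1 log2 unit, 78 lay within 1 unit and 1 was higher. The unloaded controls also had no sham surgery, so unloading and sham surgery are confounded between the control groups.

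**Figure D1:**
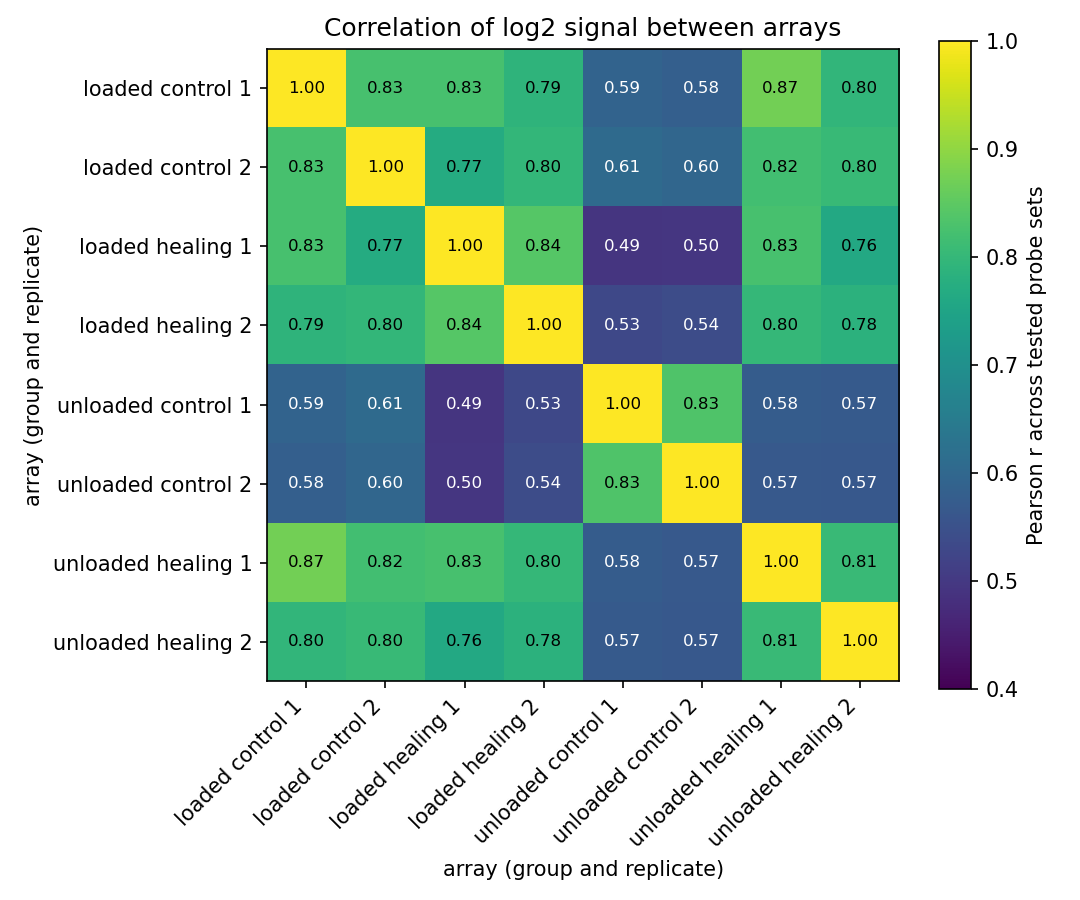
Pearson correlation of log2 signal across the 5244 tested probe sets for each pair of the 8 arrays, with colour and printed value both showing r. The unloaded control arrays correlate with the other 6 at 0.492 to 0.608, and those 6 correlate with each other at 0.761 to 0.872.

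In loaded rats, healing ligaments carried far more transcript of osteopontin, lysozyme and matrix-degrading enzymes than sham-operated ligaments. Spp1, which encodes osteopontin, a matrix protein also secreted by macrophages, rose 19.3-fold (log2 4.27 ± 0.33 SE, adjusted p = 0.000223, n = 2 arrays per group here and below). Lyz2, the lysozyme of myeloid cells, rose 8.52-fold (log2 3.09 ± 0.24, adjusted p = 0.000223), and Mmp12, the macrophage metalloelastase, rose 14.4-fold (log2 3.85 ± 0.44, adjusted p = 0.00212). Comp, a glycoprotein of tendon and ligament matrix, fell 6.67-fold (log2 -2.74 ± 0.45, adjusted p = 0.0134). In all, 54 probe sets rose and 52 fell of 5244 tested, and 65 named genes were among them. In the 4 pairwise contrasts, both arrays of the higher group lay above both arrays of the lower one for every called probe set, which selection by the test largely ensures.

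Among matrix proteases and inhibitors, 4 of 24 genes rose and 0 fell, and 6 rose and 1 fell when adjusted over the list alone. Mmp12 was joined by the collagenase Mmp13 (log2 3.20 ± 0.63), the osteoclast protease Ctsk (2.61 ± 0.49) and the lysosomal protease Ctss (2.00 ± 0.27). The list moved up as a whole (camera adjusted p = 0.000177), with adjusted p = 0.110 with an estimated correlation. Of 19 macrophage and myeloid markers 4 rose and 0 fell, the same counts as adjusted over the list alone. They were Lyz2, Ctss, the class II antigen-presentation gene RT1-Da (1.95 ± 0.23) and galectin-3, Lgals3 (1.73 ± 0.28). This list also moved up (camera adjusted p = 0.000177), with adjusted p = 0.110 with an estimated correlation. Its median was 0.10 and its mean 0.79, with 13 members higher and 6 lower. Of 32 genes of oxidative phosphorylation and the citrate cycle 2 rose and 0 fell (7 and 1 adjusted over the list alone), Atp5po by 1.74 and Cox4i1 by 1.51 log2 units. That list moved up at adjusted p = 0.00133, with adjusted p = 0.165 with an estimated correlation.

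Matrix genes moved both ways in loaded healing. Of 28 proteoglycans and matrix glycoproteins 3 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.538). Sparcl1 rose (log2 2.60 ± 0.54), while Sparc, the collagen-binding osteonectin, fell (-1.66 ± 0.17, adjusted p = 0.00121), as Comp did. Of 10 collagens 0 passed with limma over all probe sets and 3 rose adjusted over the list alone (camera adjusted p = 0.140), with log2 values of 0.89 for Col3a1 and 1.45 for Col5a2. Of 9 collagen processing genes 2 fell, by either adjustment (camera adjusted p = 0.140): Pcolce, which enhances procollagen cleavage (-2.57 ± 0.46), and the endoplasmic reticulum isomerase Ppib (-1.52 ± 0.33). Of 7 tendon and ligament fibroblast markers 1 fell, Comp, and 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.953). The median of that list was 0.23 and its mean -0.29, and camera's direction was up.

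Single genes of other kinds also fell in loaded healing, and array control probe sets for actin and GAPDH were lower there too. The actin 3' control read 1353 and 1597, against 4393 and 4955 in loaded controls and 4786 and 5235 in unloaded healing. It read 1284 and 1494 in unloaded controls. The GAPDH 3' control read 1038.5 and 842.6 in loaded healing, against 2277.5 and 2334.6 in loaded controls. The antioxidant enzyme Gpx3 (log2 -3.45), the transcription factor Nfix (-2.81), the proteasome subunit Psmb5 (-2.80), the translation factor Eef1a1 (-2.75), Nbl1 (-2.70), Capns1 (-2.62) and the ATP synthase subunit Atp5f1e (-2.21) fell. Of 43 ribosomal protein genes 1 rose and 6 fell (5 and 9 adjusted over the list alone), with Rps10 at -1.85, Rps16 at -1.63 and Rpsa at -1.53. The ribosomal list did not pass (adjusted p = 0.801, camera direction down, median 0.08, mean -0.08). Of 31 adhesion and actin cytoskeleton genes 3 rose and 1 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.293): Tuba1b, S100a4 and Tmsb4x rose, by 1.38, 1.00 and 0.80, and Actg1 fell by 1.98.

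In the other lists camera gave no call in loaded healing. Of 8 cartilage and bone markers 2 rose, Spp1 and Ctsk, by either adjustment (adjusted p = 0.139). Of 17 adipocyte and lipid genes 2 rose, by either adjustment: the lipase Lpl (1.95 ± 0.31) and the lipid carrier Apoe (1.82 ± 0.24), with a list adjusted p of 0.357, median -0.04 and direction up. Skeletal muscle markers had 1 of 35 higher, Acta1 at 1.18, and 3 adjusted over the list alone (adjusted p = 0.695). Glycolysis and hypoxia genes had 1 of 19 higher, Eno1 at 1.26, and 2 adjusted over the list alone (0.516). Heat shock and stress genes had 1 of 38 higher by either adjustment, the metallothionein Mt3 at 1.88 (0.801, median -0.04, direction up). Growth factors and receptors had 1 of 40 lower by either adjustment, Igfbp6 at -1.19 (0.357). Erythroid genes had 0 of 10 past the threshold, and 2 rose and 1 fell adjusted over the list alone (0.516). Immediate early genes had 0 of 22, and 1 rose and 1 fell adjusted over the list alone (0.953). By either adjustment 0 passed among 33 inflammatory mediators (0.574), 30 cell cycle genes (0.357), 14 myofibroblast and smooth muscle markers (0.313), 14 endothelial markers (0.357), 14 lymphocyte and mast cell markers (0.801), 15 nerve and Schwann cell markers (0.821) and 12 glucocorticoid and atrophy genes (0.953).

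The number of calls in loaded healing depended on each of its 4 arrays: limma called 37 without loaded control 1, 32 without loaded control 2, 27 without loaded healing 1 (7 higher, 20 lower) and 36 without loaded healing 2. Against 106 calls, there were 29 with a variance prior without the intensity trend (15 higher, 14 lower), 64 with median centring (32 and 32) and 70 without a filter (37 and 33). Of 42 named genes called, 6 stayed past the threshold whichever array was left out: Spp1, Lyz2, Psap, Sparc, RT1-Da and Rpsa. Under the other settings, 10 of the 42 kept their call in every one. Scaled to the spike-in controls, the median of all genes moved from -0.03 to 0.34 and the split was 84 higher to 22 lower. Other probe sets of the same genes often differed in size: of 22 for 17 called genes, 13 had the same direction and 1 passed. Psap, the precursor of lysosomal activator proteins, rose by 2.95 ± 0.19 (adjusted p = 0.000161) on its named probe set, but its other probe sets read -0.49 and -0.21. Eef1a1 read 0.17, Psmb5 0.94, Atp5f1e 0.76, Apoe -0.09 and Sparc 0.11 on another probe set each and Cox4i1 -0.58 and -0.85 on 2, and none of these passed. The 1 that passed was a further probe set of Sparc, at -1.22 (limma adjusted p = 0.0414).

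**Figure D2:**
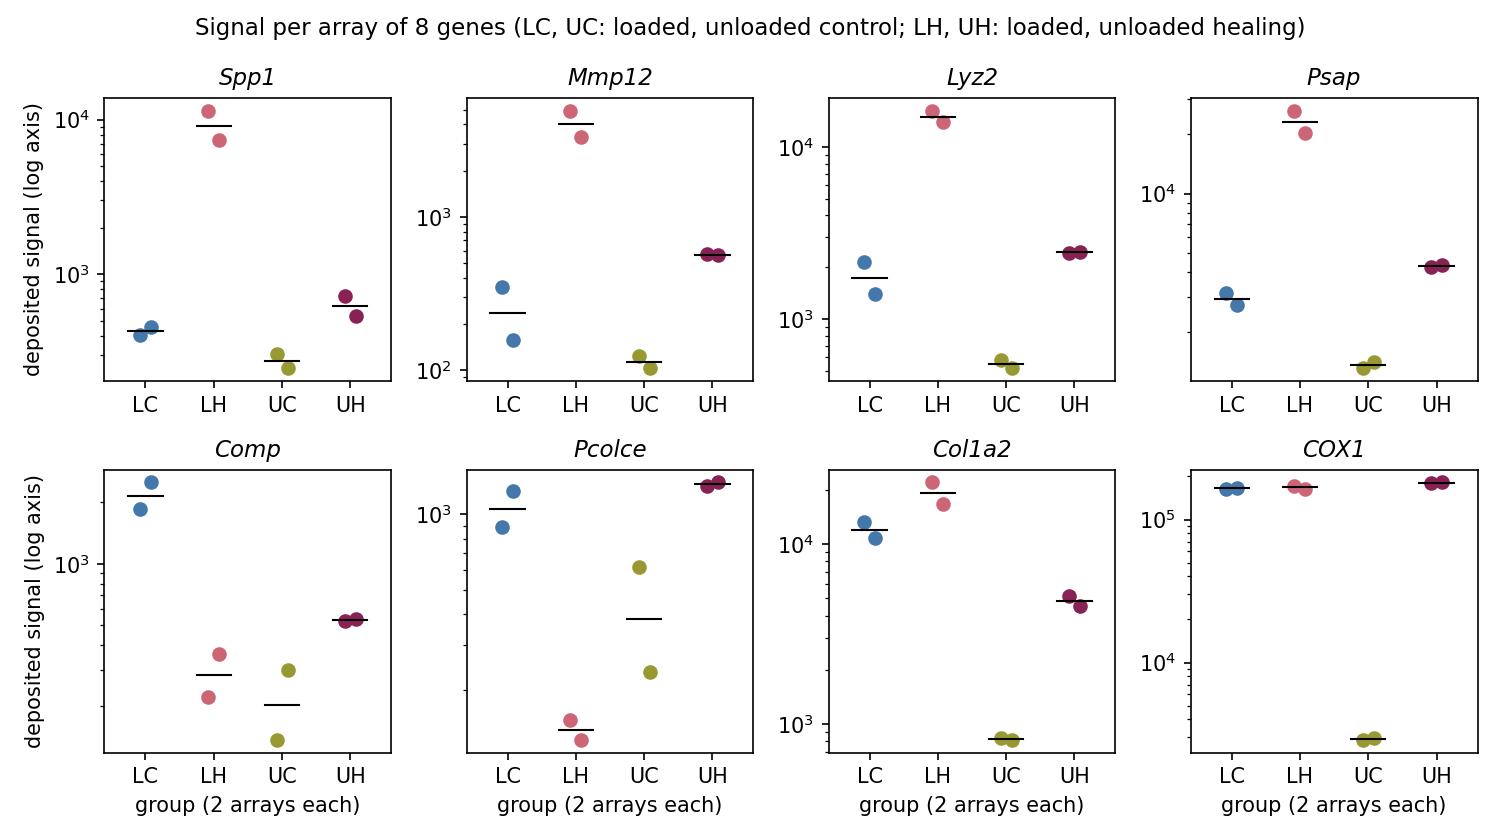
Deposited signal (log axis) of 8 named genes on each array, with 1 point per array and a line at the mean of each group of 2 (the text gives limma values). Spp1, Mmp12, Lyz2 and Psap are highest on both loaded healing arrays, and COX1 reads 2887 and 2966 on the unloaded controls and 164214 to 181707 elsewhere.

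Among healing ligaments, some macrophage, protease and collagen transcripts were lower under unloading. Spp1 fell 13.7-fold in unloaded against loaded healing (log2 -3.78 ± 0.33, adjusted p = 0.000518), Lyz2 fell 6.07-fold (-2.60 ± 0.24, adjusted p = 0.000689) and Mmp12 fell 6.68-fold (-2.74 ± 0.44, adjusted p = 0.0148). Col1a2, a chain of type I collagen, fell 3.96-fold (-1.99 ± 0.19, adjusted p = 0.000888) and the matrix glycoprotein Fn1 fell 3.81-fold (-1.93 ± 0.25, adjusted p = 0.00442), though its 2 other probe sets both read 0.56 and did not pass. Pcolce rose 7.40-fold (2.89 ± 0.46, adjusted p = 0.0148). In all, 40 probe sets rose and 45 fell, with 55 named genes among them.

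Of 10 collagens 2 fell, Col1a2 and Col3a1 (-1.20 ± 0.23, with another probe set at 0.70), and 4 fell adjusted over the list alone. The list moved down (adjusted p = 0.000113), with adjusted p = 0.0996 with an estimated correlation. Of 7 tendon and ligament fibroblast markers 1 fell, Col1a2, and 4 fell adjusted over the list alone (camera adjusted p = 0.000957). Matrix proteases and inhibitors had 2 of 24 lower, Mmp12 and Ctss (-1.43 ± 0.27), and 4 lower adjusted over the list alone (camera adjusted p = 0.000957). Of 19 macrophage and myeloid markers 4 fell, and 5 adjusted over the list alone (camera adjusted p = 0.00153, median -0.11, mean -0.58), including RT1-Da (-1.87 ± 0.23) and Lgals3 (-1.46 ± 0.28). These 3 lists also had adjusted p = 0.0996 with an estimated correlation. Of 28 proteoglycans and matrix glycoproteins 1 rose, Sparc, and 3 fell (2 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0514). Of 32 oxidative phosphorylation and citrate cycle genes 0 passed with limma over all probe sets and 3 fell adjusted over the list alone. That list moved down at camera adjusted p = 0.00928, with adjusted p = 0.181 with an estimated correlation. It did not pass without loaded healing 2 (adjusted p = 0.133) or without unloaded healing 2 (adjusted p = 0.194), nor with the probe sets of a gene averaged (0.0635).

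Of 43 ribosomal protein genes 6 rose and 0 fell under unloading in healing (9 and 1 adjusted over the list alone). The median of the list was 0.12 and its mean 0.26, with 27 members higher and 16 lower. The camera test called the list up at adjusted p = 0.0235, with adjusted p = 0.353 with an estimated correlation. With fry in one direction it did not pass (adjusted p = 0.0663). Rps10 rose by 1.97, Rpl6 by 1.95, Rps16 by 1.87 and Rpsa by 1.66 log2 units. The call of the ribosomal proteins list ended without loaded healing 2 (adjusted p = 0.214), without unloaded healing 1 (0.122) and with spike-in scaling (0.503). Eef1a1 (2.67 ± 0.45), Nbl1 (2.65 ± 0.40), Psmb5 (2.63 ± 0.51), Nfix (2.58 ± 0.45), Capns1 (2.49 ± 0.39) and the chaperone Hsp90ab1 (1.94 ± 0.34) also rose. Sparc rose by 0.90 ± 0.17 and Actg1 by 1.87 ± 0.28. The glucose transporter Slc2a1 (-3.66), the chemokine Cxcl13 (-2.82), Sparcl1 (-2.72), the surface protein Thy1 (-2.66), the Wnt antagonist Sfrp4 (-2.49), Psap (-2.40) and the RNA polymerase III subunit Polr3a (-2.33) fell. Lpl and Apoe were the 2 of 17 adipocyte and lipid genes that fell (-2.05 and -1.18). The myosin Myh4 (-1.42) and endothelial nitric oxide synthase, Nos3 (-1.49), fell as well.

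These probe sets were largely the ones that separated healing from control in loaded rats. Of 106 calls in loaded healing and 85 here, 63 were shared, all in opposite directions, 28 up with injury and down with unloading and 35 the reverse. Independent lists would share 0.463 and 0.397 of these kinds, but these contrasts are not independent, so those values are no fair reference. Both contrasts use the loaded healing arrays, with opposite sign, so shared calls tend to be opposite. Simulated data without any effect gave a correlation of -0.50 between them, against -0.65 measured across probe sets. How many calls would be shared without any effect was not simulated. The number of calls fell to 25 without loaded healing 1 (17 higher, 8 lower), 27 without loaded healing 2 (16 and 11), 50 without unloaded healing 1 (17 and 33) and 25 without unloaded healing 2 (13 and 12), and there were 59 without loaded control 1 (30 and 29). Against 85 calls, there were 16 with a variance prior without the intensity trend (9 higher, 7 lower) and 42 with median centring (22 and 20). Of 38 named genes called, 7 stayed past the threshold whichever array was left out: Spp1, Lyz2, Psap, Col1a2, Rps10, Rps16 and Rpsa. Under the other settings, 4 of the 38 kept their call in every one. With spike-in scaling, under which the median of all genes moved from 0.06 to -0.40, there were 137 calls (18 higher, 119 lower). Of 25 other probe sets of 17 called named genes, 10 had the same direction and 0 passed with limma in either direction at the adjusted threshold. Among these, Psap read 0.71 and 1.18, Apoe 1.20, Sparc -0.56, Psmb5 -0.72, Eef1a1 -0.04 and Hsp90ab1 -0.44 and -0.66, opposite in sign to the named probe sets.

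**Figure D3:**
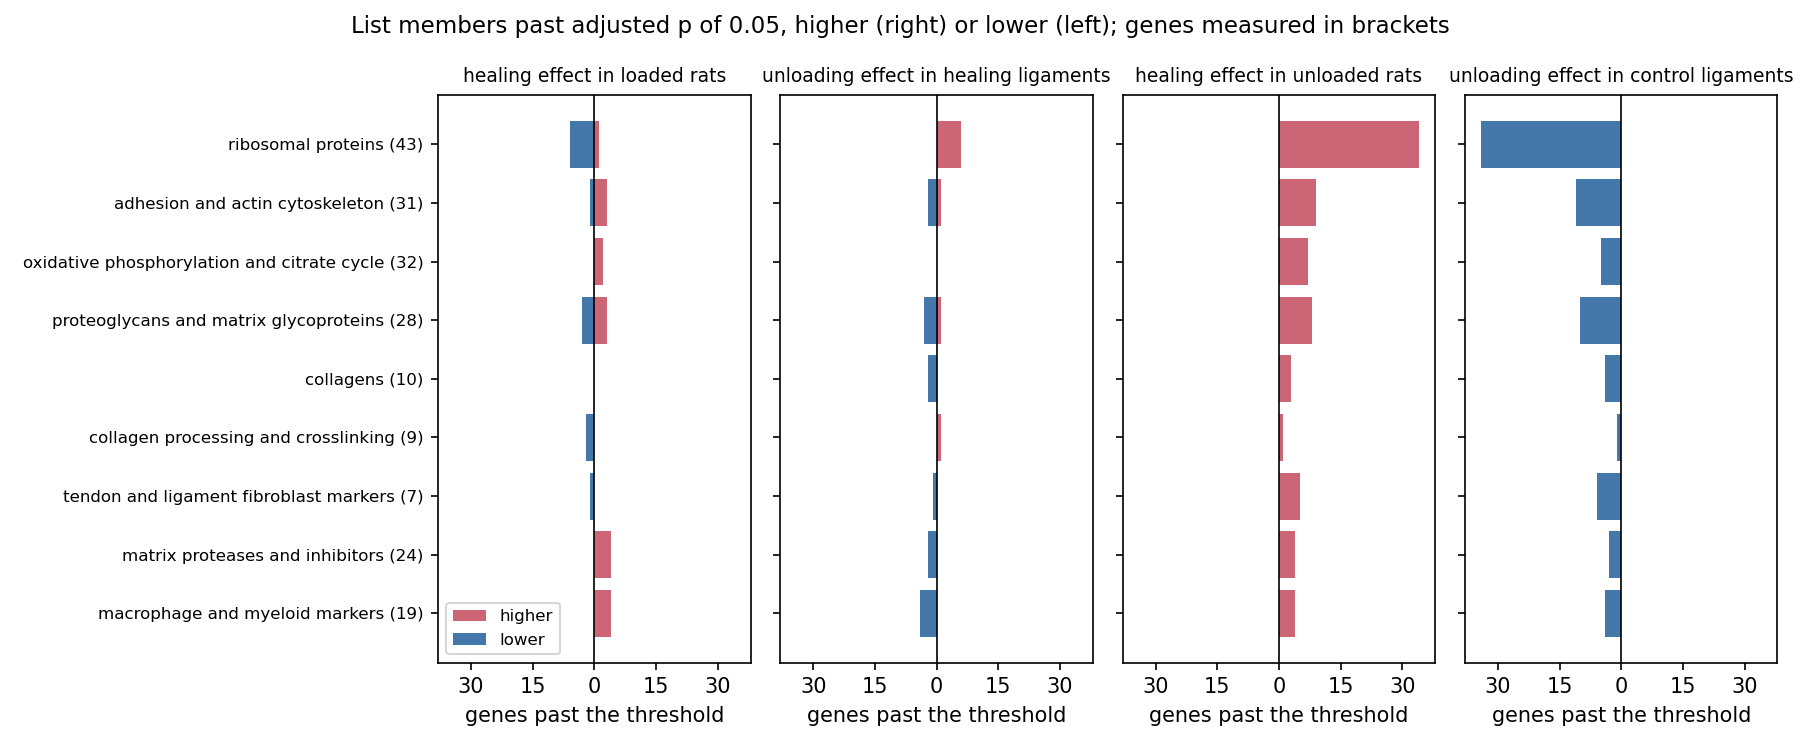
Number of genes past an adjusted p of 0.05 in 9 gene lists for 4 contrasts, with higher to the right and lower to the left and the genes measured in brackets. Ribosomal proteins stand out in the contrasts that use the unloaded controls, with 34 of 43 higher in unloaded healing and 34 of 43 lower in unloaded controls.

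In unloaded rats, ribosomal protein genes read higher as a group in healing than in control ligaments. The largest rises of single genes were those of COX3, COX1 and Col1a1. This contrast rests on the unloaded control arrays, whose 99th percentiles of signal were 5494 and 5584. Of the 336 probe sets called higher, 291 were also called lower in unloaded than in loaded controls. Between unloaded healing and loaded control limma called 4. Most of these rises thus go with low signal on the unloaded controls, and a rise with healing cannot be told apart from it. The mitochondrial cytochrome oxidase subunits COX3 and COX1 rose 73.1-fold (log2 6.19 ± 0.14, adjusted p = 1.28e-09) and 60.7-fold (5.92 ± 0.13, adjusted p = 1.28e-09). Col1a1, the main chain of type I collagen, rose 54.0-fold (5.76 ± 0.20, adjusted p = 2.46e-08) on its brightest probe set, and its other 3 probe sets read 1.94, 0.78 and 2.01 log2. Polr3a fell 7.42-fold (-2.89 ± 0.34, adjusted p = 0.000210). In all, 336 probe sets rose and 55 fell, with 218 named genes among them.

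Of 43 ribosomal protein genes 34 rose and 0 fell (35 and 0 adjusted over the list alone, median 3.17), among them Rpl11 at 5.41, Rpl13a at 5.30, Rps6 at 5.07 and Rpl4 at 5.01. The list's camera adjusted p was 4.19e-55, and adjusted p = 0.0118 with an estimated correlation. Of 7 tendon and ligament fibroblast markers 5 rose, and 7 adjusted over the list alone, including the small proteoglycan Dcn (3.32 ± 0.32) and Thbs4 (3.24 ± 0.35). Its camera adjusted p was 4.76e-11, and adjusted p = 0.0195 with an estimated correlation. Of 31 adhesion and actin cytoskeleton genes 9 rose, and 11 adjusted over the list alone, led by S100a10 (5.48), Lgals1 (4.56), Actb (3.64) and Marcks (3.62). This list had camera adjusted p = 2.39e-10, and adjusted p = 0.0195 with an estimated correlation.

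Collagens had 3 of 10 higher, Col1a1, Col3a1 (4.02) and Col1a2 (2.47), and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00959). Collagen processing had 1 of 9 higher, the crosslinking enzyme Lox (1.85), and 2 adjusted over the list alone (0.0192). For both, adjusted p = 0.154 with an estimated correlation, and the collagen processing list did not pass without unloaded healing 1 (adjusted p = 0.0626). Proteoglycans and matrix glycoproteins had 8 of 28 higher, and 10 adjusted over the list alone, with Sparc at 4.28 and Mgp at 2.78 (camera adjusted p = 8.46e-06, and adjusted p = 0.143 with an estimated correlation). Oxidative phosphorylation and the citrate cycle had 7 of 32 higher, and 8 adjusted over the list alone, with Cox4i1 at 4.35 and Cox6a1 at 2.86 (camera adjusted p = 9.93e-06, and adjusted p = 0.0565 with an estimated correlation).

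Lists without a call held single genes past the threshold in unloaded healing. Matrix proteases and inhibitors had 4 of 24 higher, and 7 adjusted over the list alone (camera adjusted p = 0.102), among them Ctsk (2.88 ± 0.49), Cst3 (2.42 ± 0.38) and Mmp12 (1.95 ± 0.44). Macrophage and myeloid markers had 4 of 19 higher (adjusted p = 0.157): Cd74 (3.56), Lgals3 (2.35), Lyz2 (2.07) and RT1-Da (1.11). Skeletal muscle markers had 6 of 35 higher (adjusted p = 0.0543), with Acta1 at 2.30 and the fast troponins Tnni2 at 2.11 and Tnnc2 at 1.84. Hemoglobin genes Hbb (3.33) and Hbb-b1 (2.74) were the 2 of 10 erythroid genes that rose. Vim (5.30) and Postn (2.27) rose among 14 myofibroblast markers (adjusted p = 0.0532), Igf1 (1.89) and Fgfr2 (1.62) among growth factors, and Mt3 (3.47) and Nupr1 (3.04) among stress genes. Falls included Homer1 (-3.12 ± 0.65), Nrg1 (-2.31 ± 0.53), Nos3 (-2.15 ± 0.31), Sox13 (-2.29 ± 0.59), Plcb2 (-2.10 ± 0.38) and the immediate early phosphatase Dusp5 (-1.24 ± 0.28). No other probe set of Homer1 (-0.31 to 0.53), Nrg1 (-0.15 and 0.84) or Nos3 (-0.88 to -0.46) passed, nor did those of Cox6a1 at -1.49 and -0.02, Igf1 at -0.36 and Lox at -0.07. Of 47 other probe sets of 29 called named genes, 38 had the same direction and 14 of them passed. With quantile normalization there were 628 calls, 391 higher and 237 lower, and the median of all genes moved from -0.23 to -0.16. With spike-in scaling that median was -0.40 and with median centring -0.03. Without unloaded healing 1 there were 361 calls, 262 higher and 99 lower, while the falls numbered 16 without unloaded control 1, 19 without unloaded control 2 and 33 with median centring. Of 60 named genes called, 38 stayed past the threshold whichever array was left out.

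Between the control groups, many of these transcripts gave far lower signal in unloaded ligaments without sham surgery than in loaded sham-operated ligaments. Whether the tissue held less of them cannot be told apart from too little RNA on the arrays or from scaling. Col1a1 fell 86.7-fold (log2 -6.44 ± 0.20, adjusted p = 1.19e-08) on its brightest probe set and read -2.75, -1.38 and -3.19 on the other 3. COX3 fell 61.6-fold (-5.95 ± 0.14, adjusted p = 1.90e-09) and COX1 fell 55.7-fold (-5.80 ± 0.13, adjusted p = 1.90e-09). Vim, the filament protein of fibroblasts, fell 52.9-fold (-5.73 ± 0.40, adjusted p = 3.77e-06). In all, 31 probe sets rose and 326 fell, with 194 named genes among them. The actin 5'/3' ratio was 0.964 and 0.634 on the unloaded control arrays, against 0.360 and 0.392 on the loaded control arrays. For GAPDH the same ratio was 0.953 and 0.712, against 0.896 and 0.790.

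Ribosomal proteins had 34 of 43 lower and 0 higher by either adjustment, with a median of -2.94, among them Rpl11 at -5.13, Rpl13a at -5.01, Rps3a at -4.84 and Rps6 at -4.79 (camera adjusted p = 2.29e-56, and adjusted p = 0.0112 with an estimated correlation). Tendon and ligament fibroblast markers had 6 of 7 lower by either adjustment, with Dcn at -4.11, Thbs4 at -3.93 and Fmod at -3.51 (camera adjusted p = 9.58e-15, and adjusted p = 0.0136 with an estimated correlation). Adhesion and actin cytoskeleton genes had 11 of 31 lower, and 1 higher and 13 lower adjusted over the list alone, with Lgals1 at -4.74, Actb at -4.04 and Tmsb4x at -3.42 (camera adjusted p = 2.24e-10, and adjusted p = 0.0194 with an estimated correlation). Collagens had 4 of 10 lower, and 1 higher and 5 lower adjusted over the list alone, with Col3a1 at -4.33, Col1a2 at -3.78 and Col5a1 at -1.27 (camera adjusted p = 8.41e-05, and adjusted p = 0.0664 with an estimated correlation). Proteoglycans and matrix glycoproteins had 10 of 28 lower, and 11 adjusted over the list alone, with Sparc at -5.04 (camera adjusted p = 6.79e-07, and adjusted p = 0.0878 with an estimated correlation). Collagen processing had 1 of 9 lower, Lox at -2.83, and 4 adjusted over the list alone (camera adjusted p = 0.00292, and adjusted p = 0.0878 with an estimated correlation). Oxidative phosphorylation had 5 of 32 lower, and 9 adjusted over the list alone, with Cox4i1 at -3.72 and Cox6a1 at -2.99 (camera adjusted p = 7.18e-05, and adjusted p = 0.0664 with an estimated correlation).

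Heat shock and stress genes had 6 of 38 lower, and 8 adjusted over the list alone, with Nupr1 at -3.86, the chaperones Hspa5 at -2.54 and Hspe1 at -2.37, and Mt3 at -2.51. The list moved down at camera adjusted p = 0.0140 although its median was 0.06 (mean -0.38), with adjusted p = 0.201 with an estimated correlation. The call of heat shock and cell stress ended without loaded control 2 (adjusted p = 0.126), without unloaded control 2 (0.102) and with quantile normalization (0.158). Macrophage and myeloid markers had 4 of 19 lower (camera adjusted p = 0.551), with Cd74 at -3.51 and Lgals3 at -2.08. Matrix proteases and inhibitors had 3 of 24 lower (0.269), with Ctsb at -2.08, Cst3 at -2.07 and Timp2 at -1.42. Igf1 (-1.80), Igfbp6 (-1.55), Anxa2 (-2.20), Postn (-2.32), Myh4 (-2.18), Acta1 (-1.29), Apoe (-2.47) and Hbb (-1.52) also fell. The named rises were Homer1 (2.52), Bpifb4 (2.47), the neurotrophin Bdnf (2.37), Kng2 (2.37), the insulin-responsive glucose transporter Slc2a4 (2.05), Kti12 (2.04), inducible nitric oxide synthase Nos2 (2.02), Scd2 (2.01), Nup62 (1.65) and Cyp2c23 (1.53). No other probe set of Homer1 (-0.17 to 0.35), Bdnf (-1.14 to 0.84), Scd2 (-1.53 and 0.24) or Nos2 (-0.28 and 0.48) passed, nor did one each of Fmod at 0.21, Hspa5 at 0.63 and Cox6a1 at 0.76. All probe sets called higher in this contrast numbered 8 without unloaded control 1, 8 without unloaded control 2 and 7 with median centring, against 31. Of 52 other probe sets of 30 called named genes, 42 had the same direction and 15 of them passed.

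The contrasts that share the unloaded control arrays mirrored each other: of 391 calls for healing in unloaded rats and 357 for unloading in controls, 302 were shared and all were opposite in sign, 291 of them up in healing. The correlation across probe sets was -0.86, against -0.50 in simulated data without any effect. With quantile normalization the control contrast had 593 calls, 207 higher and 386 lower, and the median of all genes moved from 0.23 to 0.15. That median was 0.32 with spike-in scaling and -0.01 with median centring. In a fit without unloaded healing there were 36 calls higher and 319 lower, and 34 and 282 with that scaling. In the same fit with the BioB controls added the median was 0.79 with 222 calls higher and 210 lower, and with BioB alone 1.26 with 1968 higher and 197 lower. Of 55 named genes called, 31 stayed past the threshold in every fit with an array left out.

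The healing effect differed between unloaded and loaded rats for 254 probe sets, 237 with a more positive effect in unloaded rats and 17 with a more negative one. COX3 (difference 6.18 ± 0.19 log2, adjusted p = 3.05e-08), Sparc (5.94 ± 0.24, adjusted p = 1.97e-07), COX1 (5.90 ± 0.18, adjusted p = 3.05e-08) and Col1a1 (5.52 ± 0.29, adjusted p = 8.67e-07) differed most among the named matrix and mitochondrial genes. Spp1 differed the other way (-3.21 ± 0.46, adjusted p = 0.00144), with Slc2a1 (-3.68 ± 0.86), Nos3 (-2.01 ± 0.43) and Ctss (-1.58 ± 0.38). The difference includes the unloaded control arrays, on which 121 of the 200 otherwise brightest probe sets were lower by more than 1 log2 unit.

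Ribosomal proteins had 33 of 43 with a more positive effect and 0 with a more negative one, and 34 adjusted over the list alone, led by Rpl13a (5.74), Rpl4 (5.39), Rpl11 (5.19) and Rps15 (4.90). The list's camera adjusted p was 4.39e-61, and adjusted p = 0.00953 with an estimated correlation. Tendon and ligament fibroblast markers had 6 of 7 more positive by either adjustment, with Dcn at 4.21, Comp at 3.93 and Fmod at 2.98 (camera adjusted p = 1.32e-10, and adjusted p = 0.0260 with an estimated correlation). Adhesion and actin cytoskeleton genes had 8 of 31 more positive, and 9 adjusted over the list alone, with S100a10 at 5.29, Lgals1 at 5.02 and Actb at 4.49 (camera adjusted p = 1.70e-07, and adjusted p = 0.0368 with an estimated correlation). Collagen processing had 3 of 9 more positive by either adjustment, Pcolce (4.23), Ppib (2.21) and Lox (2.17) (camera adjusted p = 0.00420, and adjusted p = 0.146 with an estimated correlation). Proteoglycans and matrix glycoproteins had 6 of 28 more positive and 1 more negative by either adjustment, with Bgn at 3.78 (camera adjusted p = 0.0240). Collagens had 3 of 10 more positive by either adjustment, with Col3a1 at 3.13 and Col1a2 at 1.79 (camera adjusted p = 0.0423). For these last lists adjusted p = 0.306 with an estimated correlation. Without loaded healing 2, unloaded control 2 or unloaded healing 1 the proteoglycans and matrix glycoproteins had adjusted p of 0.0814, 0.0557 and 0.0534, with 0.116 without a filter and 0.0621 with averaged probe sets. Collagens had 0.0811, 0.0710 and 0.102 without the same arrays, 0.0582 without loaded control 2, 0.0729 with median centring, 0.161 without a filter and 0.0993 with averaged probe sets.

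Further named differences were Nfix (4.99), Eef1a1 (4.60), Vim (4.05), Nupr1 (3.63), Cd74 (3.49), Igf1 (2.77), Anxa2 (2.67), Hbb (2.31) and Gpx3 (1.51). For Eef1a1 and Gpx3 these are other probe sets than those named in loaded healing, whose differences were 3.16 and 4.92. Quantile normalization gave 328 calls, 251 more positive and 77 more negative, with the median of all genes at -0.12 against -0.16. Spike-in scaling gave 232 calls, 184 and 48, with that median at -0.70, and median centring put it at 0.06. Of 48 named genes called, 37 stayed past the threshold in every fit with an array left out. The 17 more negative probe sets became 7 without loaded healing 1, 8 without loaded healing 2, 6 without unloaded control 2, 32 without unloaded healing 1 and 8 with median centring. Of 39 other probe sets of 25 called named genes, 33 had the same direction and 16 of them passed. Opposite in sign on another probe set were Cox6a1 (-1.16), Cd74 (-0.62), Lox (-0.48), Rps15 (-0.24), Fmod (-0.23) and Nos3 (0.54). None of these passed, nor did the other probe set of Nfix at 0.19.

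Averaged over loading, the healing effect called 316 probe sets higher and 59 lower, with 222 named genes among them. This average includes the unloaded control arrays with their low signal of abundant transcripts. Healing in unloaded rats alone had 336 probe sets higher and 55 lower, against 54 and 52 in loaded rats. Quantile normalization gave 360 higher and 176 lower, without unloaded control 1 there were 312 calls, 295 higher and 17 lower, and spike-in scaling and median centring gave 31 lower each. Leaving out another array gave 32 lower (loaded control 1), 23 (loaded control 2), 35 (loaded healing 1), 27 (unloaded control 2), 93 (unloaded healing 1) and 39 (unloaded healing 2). The median of all genes was -0.14, and -0.04 with spike-in scaling. The effects in loaded and in unloaded rats shared 37 calls of the same sign and 37 of opposite sign, and their correlation across probe sets was 0.11.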

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

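The tests of too little RNA, of scaling and of another tissue on the unloaded control arrays were chosen after the result was seen, and the test of other groupings of the arrays was set beforehand. The test of scaling first used the BioC, BioDn and CreX controls, by which scaling would have counted as excluded, and the sets with BioB were added after that value was known.

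The healing effect differed between unloaded and loaded rats for 254 probe sets by limma's interaction term. The same term separated 6 gene lists by camera, with median differences of 3.18 log2 units for ribosomal proteins, 2.98 for tendon and ligament fibroblast markers, 1.01 for collagen processing, 0.61 for adhesion and actin cytoskeleton, 0.25 for proteoglycans and matrix glycoproteins and 0.049 for collagens. With an estimated correlation the last 2 had adjusted p = 0.306 and collagen processing adjusted p = 0.146, so these 3 calls were lost. Among control probe sets left out of the comparisons, the one for 5S ribosomal RNA had a mean signal of 1476 in unloaded controls (1155 and 1796) against 458.6 in loaded controls, 3.22-fold higher. The control probe set for the B2 repeat had a mean of 1445 there (1410 and 1480) against 596.0, 2.42-fold higher.

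A pattern that goes with these differences is the low signal of abundant transcripts on the unloaded control arrays. Scaling of every array to a common mean cannot be told apart from other causes for part of the calls: of the probe sets called lower, 87.4% were still called lower when arrays were scaled to the BioC, BioDn and CreX spike-in controls (85.3% in a fit without unloaded healing), but in that smaller fit 64.1% with BioB added and 59.8% with BioB alone. Another tissue with intact RNA is argued against only as the sole cause, since ribosomal protein genes, which every tissue expresses, had a median change of -2.94. These genes are among the abundant transcripts that read low, and their fall was known when the test was chosen. Another tissue together with a technical loss of signal was not tested and stays open. Too little ligament RNA on these arrays may account for it but cannot be told apart from other causes. Of the 200 otherwise brightest probe sets, 60.5% were lower by more than 1 log2 unit, between the bounds set for and against this cause. That share counts the low signal of abundant transcripts itself, so it cannot decide what caused it. A biological effect of unloading, or of the missing sham surgery, stays open and was not tested apart from it.

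In a fit of the 4 healing against the 4 control arrays as 2 groups, limma called 0 probe sets, with 618 at an unadjusted p under 0.05, and with a count of 0 all 35 of the 35 splits of the 8 arrays necessarily give as many, so the count of splits decides nothing. That fit leaves out loading, unlike the 4-group fit with its 375 calls. The highest other split called 24 and set loaded controls with unloaded healing against loaded healing with unloaded controls. That is the grouping the interaction contrast compares, which had 254 calls in the 4-group fit, so it is part of the design.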

How the results depend on the processing

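The fits without the unloaded controls or without unloaded healing, the spike-in scalings and all fits of unloaded healing against loaded control were chosen after seeing the data, and the other alternatives were planned. Without the unloaded controls limma called 115 probe sets for loaded healing (97 shared with the 106 reported) and 97 for unloading in healing (80 shared with 85). Quantile normalization gave 628 calls for healing in unloaded rats and 593 for unloading in controls. Median centring gave 64 for loaded healing and 42 for unloading in healing, a variance prior without the intensity trend 29 and 16, and spike-in scaling 137 for unloading in healing. Scaling to the BioB controls alone gave 2165 for unloading in controls. Without a filter loaded healing had 70 calls. The cause was not tested. Leaving out each array gave 27 to 94 calls for loaded healing, 25 to 83 for unloading in healing, 318 to 368 for healing in unloaded rats, 282 to 360 for unloading in controls, 215 to 245 for the interaction, 264 to 365 for the averaged effect and 0 to 6 for unloaded healing against loaded control (4 in the full fit and 7 with a replicate term, and at an unadjusted p under 0.05 limma gave 280 to 319 where 0 were called).

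Gene lists past the threshold numbered 3 in loaded healing, 7 in unloaded healing, 6 for unloading in healing, 8 for unloading in controls and 6 for the interaction. With an estimated correlation these were 0, 3, 0, 3 and 3 by camera (3, 7, 5, 7 and 4 lists at an unadjusted p under 0.05), with fry in one direction 5, 11, 4, 10 and 9, and with fry in either direction 18, 22, 17, 17 and 17. fry tests each list alone and does not compare it with other genes. Without a filter the loaded healing count was 5. Leaving out each array gave 3 to 3, 6 to 9, 5 to 7, 7 to 8 and 4 to 7 lists.

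The 243 called results of named genes kept their call in 2385 of 2689 values under other settings and in 1439 of 1944 with an array left out, and 0 changed sign in the limma fits. The 78 results given as values passed the threshold in 25 of 849 and 8 of 624. The sign changed in 3 values of 2 genes: Cd79b in loaded healing, at 0.28 without loaded control 2 and 0.18 without loaded healing 1 (range -1.63 to 0.28), and Mstn for unloading in healing, at 0.083 without unloaded healing 1 (range -1.81 to 0.083). Replicate deviations correlated at 0.159 to 0.204 between loaded control, loaded healing and unloaded healing and at 0.001 to 0.014 with unloaded controls, so the numbers were not taken to pair all samples, though structure shared by replicate number in those 3 groups is not excluded. A term for replicate number gave 123, 443, 102, 393, 270 and 419 calls for loaded healing, healing in unloaded rats, unloading in healing, unloading in controls, the interaction and the average. With 2 arrays per group, 8% of simulated changes of 1 log2 unit in loaded healing were recovered, so small changes were mostly beyond reach.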

Other observations

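The comparison of unloaded healing with loaded control and the tests on it of exchanged labels, and all tests of lower probe sets in loaded healing, were chosen after the result was seen. The test for uninjured ligament was set before its own result was seen, though after the closeness of those groups. The bound of the test of other probe sets was changed after its value was known, from one on the median to one on the quartiles. Under the first bound that explanation would have counted as excluded.

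Between unloaded healing and loaded sham-operated ligaments, limma called 4 probe sets, 3 higher and 1 lower, with 291 at an unadjusted p under 0.05. A term for replicate number gave 7. Leaving out an array gave 0 calls without loaded control 1, loaded control 2 or unloaded healing 2 (319, 303 and 280 at an unadjusted p under 0.05), 6 without unloaded healing 1, and 1 without each of the other 4 arrays. Hemoglobin beta rose in Hbb-b1 (log2 2.00 ± 0.26, adjusted p = 0.0445) and in a probe set shared by several beta globin genes (1.78 ± 0.24, adjusted p = 0.0445). A probe set shared by the fast and perinatal myosins Myh2, Myh1 and Myh8 rose by 2.85 ± 0.28 (adjusted p = 0.00816), and Polr3a fell by 2.38 ± 0.34 (adjusted p = 0.0477). These 4 fall outside the rule for named genes and are all that passed.

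This closeness raises the question of whether the arrays labelled unloaded healing carry the wound response. Probe sets raised in loaded healing against 1 loaded control array (333 and 355, by the choice of array) had medians of -0.013 and 0.013 in unloaded healing against the other loaded control array, at percentiles 76.0 and 51.3 of 10000 random lists matched on signal. The loaded healing arrays themselves gave 0.80 and 0.82. The probe sets were chosen on those same arrays, so selection favours high values there and these are no independent measure. The medians in unloaded healing may mean that the arrays labelled unloaded healing hold uninjured ligament. A smaller wound response under unloading would read the same and stays open. Exchanged labels of unloaded healing and unloaded control, taken alone, are argued against: the same probe sets had medians of -0.12 and -0.32 in unloaded controls, both at percentile 0 of the random lists, though an exchange together with too little RNA on those arrays was not tested.

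Some probe sets called lower in loaded healing, such as those of Eef1a1 and Psmb5, belong to genes whose other probe set was not lower (0.17 and 0.94). A lower share of ribosomal protein transcripts as a class is argued against, since their median change was 0.081. Fewer transcripts of the genes called lower may be the cause but cannot be told apart from effects of single probe sets, such as probe sequence or GC content, which were not tested. The 23 other probe sets of 16 such genes had a median of -0.43 (quartiles -1.07 and 0.14) against -1.82 for the called ones, and 2 of them were called lower too. The called probe set of each gene was the one with the smallest p-value, which favours large changes. How much of the gap comes from that selection was not tested. The genes called higher were alike in this, with a median of 0.19 for 26 other probe sets against 1.95 for the called ones and 14 of the 26 in the same direction.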
